A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

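Total RNA from wild-type, sfp1, ifh1 and fhl1 knockout cells in exponential growth without treatment was sequenced from directional libraries, with 1 sample per genotype. The authors deposited 1 table of FPKM values with a lower and an upper bound for each gene and genotype. The table name mentions 2 replicates, but how these were combined is not given in the sources used here. Per the submitters' processing notes, TopHat2 2.0.9 and Cufflinks 2.1.1 were used; their roles, the genome build and the annotation are not given in the sources used here. The columns named crf1d were taken as the ifh1 knockout, because crf1 is a synonym of ifh1 in the reference annotation, and the level of the gene itself was read as a check.

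The table held 5129 gene models, of which 5111 were found in the reference annotation used here (ASM294v3), 4955 with the same coding boundaries. Starts were made 1-based. Gene lengths were coding lengths, as 99.53% were multiples of 3. In all 4 genotypes 215 genes were listed at 0, among them sty1, dcp2, adh1 and all 11 mitochondrial genes, so that these could not be compared. Strand use in counting, and the sharing of reads between the near-identical copies of ribosomal protein genes or between overlapping genes, are not given in the sources used here, and such genes are uncertain for that reason.

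Sums of the deposited FPKM were 3261902, 2771939, 2766780 and 2813930 in wild type and the sfp1, ifh1 and fhl1 knockouts. FPKM of short genes were raised by an effective length. The median ratio of FPKM to the midpoint of its bounds was 7.79, 7.36, 6.68 and 9.38 at 150 to 300 bp, 2.21, 2.12, 2.11 and 2.32 at 300 to 500 bp, and 1.00 from 2000 bp on. The genes rpl4101 and rpl4102, both very short, held 41.8, 46.5, 52.0 and 44.0% of all FPKM. Of 24515 bounds under 500 fragments, 99.45% lay within 0.05 of a whole multiple of a step, which gave 5431616, 4520149, 4275084 and 4655971 fragments at the midpoints on an assumed common scale. The true depth is unknown. The half-width of the bounds was 32.87, 32.56, 32.09 and 32.68% of the midpoint above 1000 fragments and 78.95, 79.49, 80.0 and 80.0% at 5 to 20 fragments.

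Values were compared as log2(FPKM + 1) without further scaling, since size factors by the median of ratios were 1.005, 0.9995, 0.9891 and 1.021. Genes with a mean of at least 1 FPKM over the 4 genotypes were kept (4761). The design, written before the data were examined, allowed for replicate columns. None were present, so its branch for single values was used: a 2-fold limit for single genes, no test, and no error of any ratio. In 100 simulated tables with no difference between genotypes, built from the bounds, a mean of 74.3 genes was at least 2-fold higher and 74.1 at least 2-fold lower, 18.8 and 19.2 of them with bounds apart. Among 2053 genes of at least 1200 bp and more than 20 FPKM, the observed variance of the log2 ratio to wild type was 0.194, 0.134 and 0.0886 in the sfp1, ifh1 and fhl1 knockouts, against 0.111, 0.111 and 0.112 computed from the bounds, so the bounds were wider than the spread seen in the fhl1 knockout.

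Gene lists were fixed by name for ribosome production, translation, nutrient response, stress, metabolism and cell cycle, and 27 of 29 had measured members. Other names were accepted for members, which also brought in genes that do not belong. These were rlp7 in the large-subunit and rpl3802 in the small-subunit list (it is in the large-subunit list as well, so that the combined list has 142 genes). Others were 6 genes in the RNA polymerase I list, rpn11 and tip1 in the biogenesis list and mcp6 in the tRNA synthetase list. Further ones were pim1 in the nitrogen list, tdh1 in the core stress list, and doa10 and mrs6 in the mating list. The median log2 ratio of each list was placed among medians of 10000 random lists of the same size drawn from 20 bins of mean expression, and a list was called outside the range beyond the central 95%. Members of a list that share their regulation are not independent, which random lists do not reflect. The naming rule fixed in the design took the largest log2 ratios each way and the largest members of lists outside their range, in the direction of the list. The largest ratios whose bounds were apart (10 each way, 5 between knockouts) were added after the data were seen.

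The procedure was tested on simulated data, built from the geometric mean of the genotypes and the spread of the bounds, with 200 changed among 4717 genes. Genes set at a log2 difference of 2 or more either way were found in 100% of cases, at −1.5 in 92.0%, at 1.5 in 84.0%, at −0.6 in 20.0% and at 0.6 in 12.0%, while 3.25% of unchanged genes passed the limit. A list of 40 genes shifted by −0.5 was found at −0.47, and 5 of 100 unshifted lists fell outside the range. Alternatives covered the pseudocount, the expression minimum, scaling, and, added after the data were seen, midpoints of the bounds, genes of at least 300 bp, bounds apart, genes away from the deleted loci, random lists matched on length or drawn outside ribosomal protein genes, summed gene copies and current symbols alone. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.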

Results

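Exponentially growing, untreated fission yeast cells were profiled by RNA sequencing of total RNA in 4 genotypes: wild type and knockouts of sfp1, ifh1 and fhl1. The question was which genes of ribosome production, growth and nutrient response differ in level when each of these 3 transcription regulators is missing. The table gave 1 FPKM value per gene and genotype with a lower and an upper bound, so there were no replicate values and no replicate check was possible. Differences are therefore given as log2 ratios of FPKM + 1, with a 2-fold limit for single genes. Gene lists are placed by the percentile of their median among 10000 random lists of genes with matched mean expression. These percentiles describe the 4 columns of values and say nothing about how far other cultures of the same genotypes would differ.

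The deleted genes were read first, as a check of the labels. The sfp1 gene (SPAC16.05c, chromosome I 4432304 to 4433632) was listed at 0.0818 FPKM in the sfp1 knockout, against 261.0 in wild type, 270.3 in the ifh1 knockout and 256.9 in the fhl1 knockout. The ifh1 gene (SPAC22H10.11c, also named crf1, chromosome I 2392370 to 2394259) stood at 0.556 FPKM in its own knockout and at 127.5 in wild type, 105.3 in the sfp1 knockout and 117.9 in the fhl1 knockout. The fhl1 gene (SPAC1142.08, chromosome I 3639988 to 3642219) stood at 0.0509 FPKM in its own knockout and at 53.8 in wild type, 50.7 in the sfp1 knockout and 45.1 in the ifh1 knockout. Each of the 3 genes was thus near 0 in the knockout named after it and nowhere else, with log2 values of −7.92 for sfp1, −6.37 for ifh1 and −5.70 for fhl1 against wild type.

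**Figure D1:**
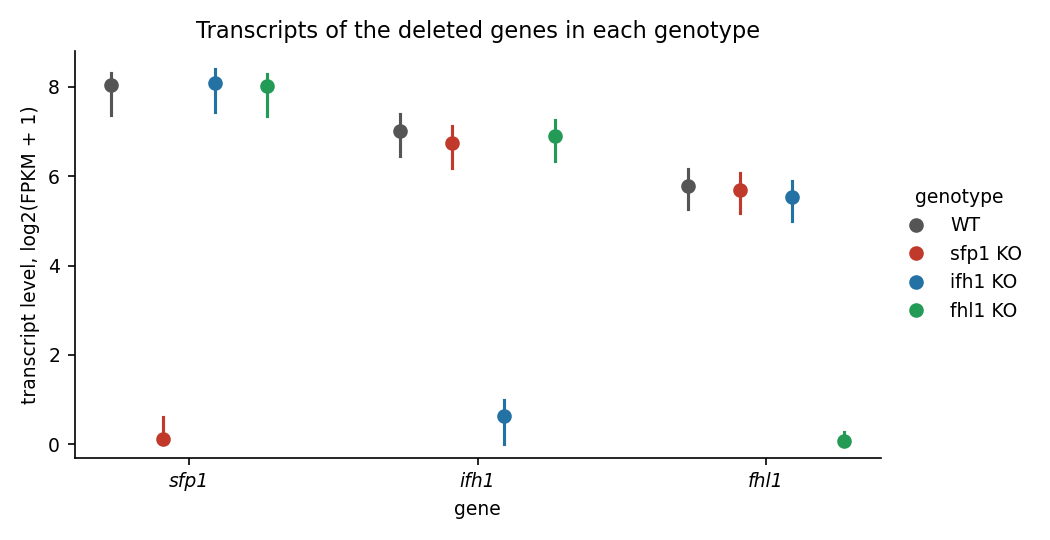
Level of sfp1, ifh1 and fhl1 in the 4 genotypes as log2(FPKM + 1), with vertical bars for the authors' lower and upper bounds. Each gene lay near 0 in its own knockout.

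The first comparison, sfp1 knockout against wild type, asked which genes differ in level when sfp1 is missing. Genes for making ribosomes were lower as a group: all 120 measured ribosome biogenesis factors were below their wild-type level, with a median log2 ratio of −0.56. Fibrillarin (fib1), the methyltransferase that modifies ribosomal RNA, was at 264.7 FPKM against 808.0, and rlp24, a factor of the large subunit precursor, at 209.2 against 515.6 (log2 −1.61 and −1.30). The 142 measured cytosolic ribosomal protein genes had a median of −0.59, with 137 below 0, but only 3 of them were at least 2-fold lower. The RNA polymerase I list and translation factors were also lower, at medians of −0.56 and −0.43.

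Among the genes of the large-subunit ribosomal protein list (87 measured, median −0.57, with the biogenesis gene rlp7 counted in under another name), rpp202 was at 2772 FPKM against 6093, rpl2701 at 3755 against 7931 and rpl1002 at 1256 against 2303 (log2 −1.14, −1.08 and −0.87). The small-subunit list (56 measured, median −0.62) held rpl3802, a large-subunit gene, under another name, and its other 55 genes, with the same median, included rps2 at 2991 FPKM against 6001, rps1401 at −0.88 and rps1402 at −0.84. The RNA polymerase I list held 22 genes, but 6 came in through other names and are not polymerase genes: the ribosomal P proteins rpp101, rpp201 and rpp203, the replication factor genes ssb1 and ssb2, and the nuclease gene pnu1. Without them the median was −0.60, with 13 of 16 genes below 0, such as nuc1, the largest subunit (154.8 against 333.6 FPKM), and rpa12 (−1.14). Of the 37 translation factor genes, 36 were below 0, with tif213, the gamma subunit of eIF2, at −1.08 and tif5 at −1.08. The cytosolic tRNA synthetase list (20 genes, among them under another name mcp6, which is no synthetase gene) had a median of −0.34, with the lysine tRNA ligase gene krs1 at 453.3 against 983.2 FPKM and mrs1, an arginine tRNA ligase gene, at −1.03. These 5 medians, and those of all ribosomal protein genes and of biogenesis factors, were below the central 95% of matched random lists. The tRNA synthetase median, at the 2.49th percentile, was inside it under several other settings, among them the 18 genes found under current symbols (4.14th percentile).

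In the opposite direction, 26 of 28 autophagy genes were above 0 (median 0.30), with atg12 at 2.18 and atg6, a beclin family gene, at 1.07. Core stress response genes had a median of 0.40, with 14 of 19 above 0. Among them the glutathione S-transferase gene gst2 was at 536.6 FPKM against 122.6 (log2 2.12), and the 153 bp metallothionein gene zym1 was at 320.9 in the knockout and listed at 0 in wild type. The zym1 value was a weak one, as its bounds in the knockout were 0 and 10.9. Genes of respiration and the citric acid cycle (39 measured, 27 above 0) and of the mitochondrial ribosome (61 measured) had medians of 0.07 and 0.04, above those of matched lists. Examples were cox7 (0.97) and qcr9 (0.59), and img2 (0.74) and mrpl44 (0.73). The mitochondrial ribosome call ended, here and in the ifh1 knockout, when random lists were also matched on gene length. Nitrogen-starvation and uptake genes (−0.14), heat shock genes (−0.30) and mating and meiosis genes (0.19) lay inside their random ranges. Glycolysis genes (−0.55, 13 of 15 below 0) were inside as well, but below when random lists were drawn outside ribosomal protein genes (0.14th percentile) or also matched on length (0.64th).

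Of 4761 genes with a mean of at least 1 FPKM, 148 were at least 2-fold higher and 118 at least 2-fold lower in the sfp1 knockout, while simulated tables without any difference gave means of 74.3 and 74.1. The fixed naming rule took 11 genes listed at 0 in one genotype, all of 270 bp or less, where short-gene FPKM values are least certain. Listed at 0 in wild type were SPAPB1A11.05 (431.4 FPKM in the knockout), SPBC21B10.15 (85.2), SPBC2A9.14 (58.1), SPBC713.14c (18.0), SPAC4H3.17 (15.9), lam4 (11.2), SPAPB15E9.06 (10.2) and zym1. Listed at 0 in the knockout were the M-factor precursor gene mfm3 (903.1 in wild type), min8 (33.3) and SPAC922.09 (22.6). The same rule named aat1, an amino acid permease gene (34.6 against 167.9 FPKM, −2.25), str3, a siderophore iron transporter gene (−1.98), the zinc finger gene SPAC683.02c (−1.88), SPAC144.01 (−2.21) and SPCC594.03 (−2.09).

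A second set was chosen after the values were seen, as the largest differences each way whose bounds lay apart. Higher genes in this set were SPBPB2B2.06c (299.2 against 45.3 FPKM, 2.70), rtc3 (2.63), the melibiase gene mel1 (2.63), gdh2, the NAD-dependent glutamate dehydrogenase gene (524.5 against 90.9 FPKM), SPAC27D7.11c (2.47), say1 (2.41), aca1 (2.27), mug14 (29.9 against 5.70 FPKM), the amino acid permease gene nrg1 (2.13) and SPBPB2B2.05 (45.3 against 9.62 FPKM). Lower genes, besides aat1, str3, SPAC683.02c and fib1, were the4 (−1.81), the purine nucleoside transporter gene SPCC285.05 (−1.80), the RNA helicase gene dbp2 (199.1 against 672.4 FPKM, −1.75), met1 (−1.71), the cysteine transporter gene SPBPB10D8.01 (−1.56) and efm6 (−1.54). Bounds lay apart for 49 of the higher and 64 of the lower genes.

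The size of the ribosomal protein difference depended on scaling. With quantile normalization, which forces equal distributions on the genotypes, the median of all ribosomal protein genes was −0.11 in the sfp1 knockout, −0.17 in the ifh1 knockout and −0.12 in the fhl1 knockout. In the sfp1 knockout the large-subunit (−0.10) and small-subunit (−0.12) lists were then inside their random ranges. Random lists for each subunit list could hold ribosomal protein genes of the other subunit. The combined list of ribosomal protein genes, whose random lists held none of them, stayed below its range in each knockout. Scaling to the sum of FPKM outside ribosomal protein genes put the median of all genes at 0.19, 0.28 and 0.15 in the sfp1, ifh1 and fhl1 knockouts. Relative to that median of all genes, the ribosomal protein medians were −0.57, −0.92 and −0.59. With that scaling, genes at the 2-fold limit were 209 higher and 56 lower in the sfp1 knockout (78.9% higher, against 55.6%), 153 and 54 in the ifh1 knockout (73.9% against 36.2%) and 147 and 28 in the fhl1 knockout (84.0% against 74.5%). Biogenesis factors in the sfp1 knockout were at −0.50 with quantile normalization and, with scaling to that sum, at −0.55 relative to the median of all genes. The same 2 values for the RNA polymerase I list of 22 genes were −0.23 and −0.54, and for translation factors −0.20 and −0.41.

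The comparison of the ifh1 knockout with wild type asked which genes differ in level when ifh1 is missing, and of the fixed lists, ribosomal proteins held the most genes at least 2-fold lower. Their log2 ratio had a median of −0.94, with 138 of 142 below 0. Of the 134 genes at least 2-fold lower, 58 were ribosomal protein genes. For example, rps1402 was at 2382 FPKM against 7895 and rpl1603 at 67.3 against 293.3 (log2 −1.73 and −2.11). Ribosome biogenesis factors lay on the other side: their median was 0.10, above the random range (−0.11 to −0.01), with 84 of 120 above 0, among them rrp8 (82.5 against 53.1 FPKM, 0.63) and nop52 (0.62).

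Large-subunit genes (median −0.87, 31 of 87 at least 2-fold lower) included rpl3002 (140.3 against 414.8 FPKM, −1.56) and rpl2401 (1593 against 4847 FPKM). The small-subunit list had a median of −0.98, with all 56 genes (55 without rpl3802) below 0 and 27 at least 2-fold lower, among them rps1701 (1404 against 3925 FPKM, −1.48) and rps2601 (1713 against 4999.8 FPKM). Glycolysis and fermentation genes had a median of −0.93, with 13 of 15 below 0 and 7 at least 2-fold lower. Among them were the glyceraldehyde 3-phosphate dehydrogenase gene tdh1 (9514 against 25191 FPKM) and the enolase gene eno101 (4903 against 11443 FPKM, −1.22). With quantile normalization the glycolysis median was −0.25, and without the expression minimum the list was inside its range. Iron response genes (12 measured, median −0.32), with fio1 at −1.37 and fip1 at −0.85, were below matched lists. So were all 9 genes of the mating-type and auxotrophic marker list (−0.43), such as lys3 (−0.85) and lys1 (−0.83), although that call ended when random lists were also matched on length. The flocculation list had a median of −0.30, with pfl7 at −0.77 and pfl2 at −0.53 (above 0 with quantile normalization), and was inside its range with quantile normalization.

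Above matched lists were nitrogen-starvation and amino acid uptake genes (median 0.18, 14 of 18 above 0, or 0.24 and 13 of 16 under current symbols, without ape4 and the Ran exchange factor gene pim1), with the peptide transporter gene ptr2 at 0.91 and isp4 at 1.45. Core stress response genes had a median of 0.28, with 12 of 19 above 0. The catalase gene ctt1 was at 79.2 FPKM against 39.9 (0.97) and sro1 at 0.84, while tdh1, which this list holds under another name, was lower. Thiamine response genes had a median of 0.09, with thi9 at 0.85 and bsu1 at 0.61, and were inside the range with quantile normalization or midpoints of the bounds. The mitochondrial ribosome list stood at 0.08, with mrpl44 at 0.84 and mrpl27 at 0.70. The respiration median of −0.03 was above matched lists, with qcr9 at 0.73 and atp15 at 0.72, but its sign was positive with quantile normalization (0.14) and with values taken from the midpoints of the bounds (0.06). RNA polymerase I (−0.03, and 0.06 without the 6 genes under other names), translation factor (−0.11) and autophagy (−0.02) lists lay inside their random ranges.

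Of the genes at the 2-fold limit, 76 were higher and 134 lower. With quantile normalization these were 67 and 62 (51.9% higher, against 36.2%). Bounds lay apart for 15 higher and 59 lower genes, 32 of the latter for ribosomal proteins. Simulated tables without any difference gave means of 74.3 higher and 74.1 lower genes, 18.8 and 19.2 of them with bounds apart. The 76 higher genes were thus near that mean, and the 15 with bounds apart were below it. By the fixed rule, SPAC27E2.14 (4472 FPKM in wild type), mfm3 (903.1), prl65 (37.7), SPAC922.09 (22.6) and SPCC18.20 (20.8) were listed at 0 in the knockout. SPBC21B10.15 (40.8 in the knockout), nce101 (30.0), SPCC4F11.05 (23.5) and SPAPB15E9.06 (10.9) were listed at 0 in wild type. The rule also named mei2, an RNA-binding protein gene of meiosis (47.5 against 8.32 FPKM, 2.38), mcp7 (2.03), emr1 (1.92), SPBPB2B2.05 (42.2 against 9.62 FPKM), the cysteine transporter gene SPBPB10D8.01 (7.57 against 113.2 FPKM), rpl1603 and the homocysteine synthase gene met17 (303.1 against 1184 FPKM, −1.96). Chosen after the values were seen were, among higher genes, the polyubiquitin gene ubi4 (268.0 against 77.8 FPKM, 1.77), SPCC794.04c (1.70), SPBPB2B2.06c (139.2 against 45.3 FPKM), isp4, SPAC22F8.05 (1.39), nrg1 (1.39) and SPAC1039.01 (1.09). Lower genes chosen in this way were the biotin transporter gene vht1 (272.8 against 1046 FPKM), oga1 (778.9 against 2879 FPKM), SPAC27D7.09c (−1.86) and SPAC8E11.10 (−1.55).

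The fhl1 knockout against wild type addressed the same question for fhl1. Ribosomal protein genes were lower here too, with a median of −0.57 and 135 of 142 below 0, but 9 were at least 2-fold lower. With the gene copies of each ribosomal protein summed into 80 families, 0 families were at least 2-fold lower here (median −0.54, 76 below 0). In the sfp1 and ifh1 knockouts 1 and 31 families were (medians −0.60 and −0.91). Biogenesis factors had a median of −0.11, below the random range (percentile 0), with 84 of 120 below 0, including ltv1 (71.3 against 118.2 FPKM) and fib1 (490.3 against 808.0 FPKM), both at −0.72. That small biogenesis difference became 0.02 with scaling to the sum outside ribosomal protein genes, and was then −0.13 relative to the median of all genes. In the nitrogen-starvation and amino acid uptake list, 16 of 18 genes were above 0 and 4 at least 2-fold higher (median 0.37; 15 of 16 under current symbols), with isp4 at 185.6 FPKM against 39.2 and ptr2 at 143.0 against 43.9 (2.21 and 1.68).

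Large-subunit genes (5 of 87 at least 2-fold lower) included rpl1002 at −1.20 and rpl2401 at −1.17. Small-subunit genes (median −0.59, 4 of 56 at least 2-fold lower) included rps2601 at −1.18, rps001 at 1685 against 3615 FPKM and rps1801 at −1.01. The ribosomal protein gene copy rpl1603 was at 72.5 FPKM against 293.3. Iron response (−0.29, fio1 −1.15) and marker genes (−0.29, lys1 −0.46, lys3 −0.44) were below matched lists, the latter no longer when these were also matched on length. Core stress response genes had a median of 0.51, with 15 of 19 above 0, among them hsp9 (2050.1 against 684.1 FPKM, 1.58) and, with the same weak bounds as in the sfp1 knockout, zym1 (157.1 FPKM, listed at 0 in wild type). Respiration genes had a median of 0.11, with 27 of 39 above 0, including cox7 (0.91) and atp15 (0.77). RNA polymerase I (−0.11, and −0.07 without the 6 genes under other names), translation factor (−0.14) and autophagy (0.21) lists lay inside their random ranges. Glycolysis genes (−0.50, 13 of 15 below 0) were inside too, but below when random lists were drawn outside ribosomal protein genes (percentile 0.02), were also matched on length (0.04), or with quantile normalization (1.69) or no expression minimum (1.17).

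Of 165 genes at the 2-fold limit, 42 were lower and the rest higher, with bounds apart for 14 and 21. Simulated tables without any difference gave means of 74.1 lower and 74.3 higher genes, 19.2 and 18.8 of them with bounds apart. The lower counts were thus below those means, and the 21 higher genes with bounds apart were near theirs. For this knockout the bounds gave more variance than was seen among long genes (0.112 against 0.0886). The simulated means may therefore be too high, and they cannot show that single differences were no more than noise. Of the higher genes, 43 were shorter than 300 bp and 25 were listed at 0 in one genotype. By the fixed rule, SPAC11D3.20 (14227 FPKM, 87 bp), SPCC417.03 (241.2), SPBC21B10.15 (163.6), nce101 (122.3), lam4 (29.2), SPBC2A9.14 (16.3), SPAC4H3.17 (14.9) and zym1 were listed at 0 in wild type. SPBC336.16 and SPAC922.09 (both 22.6 FPKM in wild type), SPCC18.20 (20.8) and SPAP27G11.11c (14.0) were listed at 0 in the knockout. The rule also named the cysteine transporter gene SPBPB10D8.01 (−2.13), rpl1603, SPBPB2B2.08 (−1.64) and met17 (−1.46). Chosen after the values were seen were rtc3 (2.80), vps32, which encodes an ESCRT-III subunit (617.2 against 107.7 FPKM, 2.51), mei2 (2.15), SPCC794.04c (1.73), SPAC22F8.05 (1.65), SPAC637.03 (1.59), ubi4 (1.54) and nrg1 (12.6 against 3.56 FPKM) among higher genes. Among lower genes they were SPAC8E11.10 (−1.42), str3 (−1.26), met1 (−1.26) and rpl2701 (−1.17).

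Other lists lay inside their random ranges in each knockout against wild type, and their medians are given in the order sfp1, ifh1 and fhl1. Histone genes stood at −0.29, −0.22 and −0.11, G1/S genes at −0.03, −0.08 and 0.01, and mitosis and separation genes at 0.07, −0.16 and 0.10. Hexose transporters stood at −0.14, −0.25 and 0.33, phosphate response genes at −0.09, 0.04 and −0.09, proteasome subunits at 0.01, −0.04 and 0.03, TORC1 pathway genes at 0.05, −0.03 and 0.03, and RNA polymerase III genes at −0.13, 0.02 and −0.05. The heat shock list stood at −0.31 in the ifh1 knockout and −0.01 in the fhl1 knockout, tRNA synthetase genes at −0.28 and −0.18, and mating and meiosis genes at 0.15 and 0.14. Some of these calls moved with the setting: with quantile normalization proteasome subunits in the sfp1 knockout (0.15) and heat shock genes in the fhl1 knockout (0.15) were above and RNA polymerase III genes in the fhl1 knockout (−0.15) below their ranges. With random lists also matched on length, hexose transporters and mitosis and separation genes in the fhl1 knockout and translation factors in the ifh1 knockout were above. The tRNA synthetase list was below in the fhl1 knockout at a mean of at least 10 FPKM and in the ifh1 knockout with midpoints of the bounds. Tf2 retrotransposons had 1 measured gene, at 1.17, −0.75 and 0.04.

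**Figure D2:**
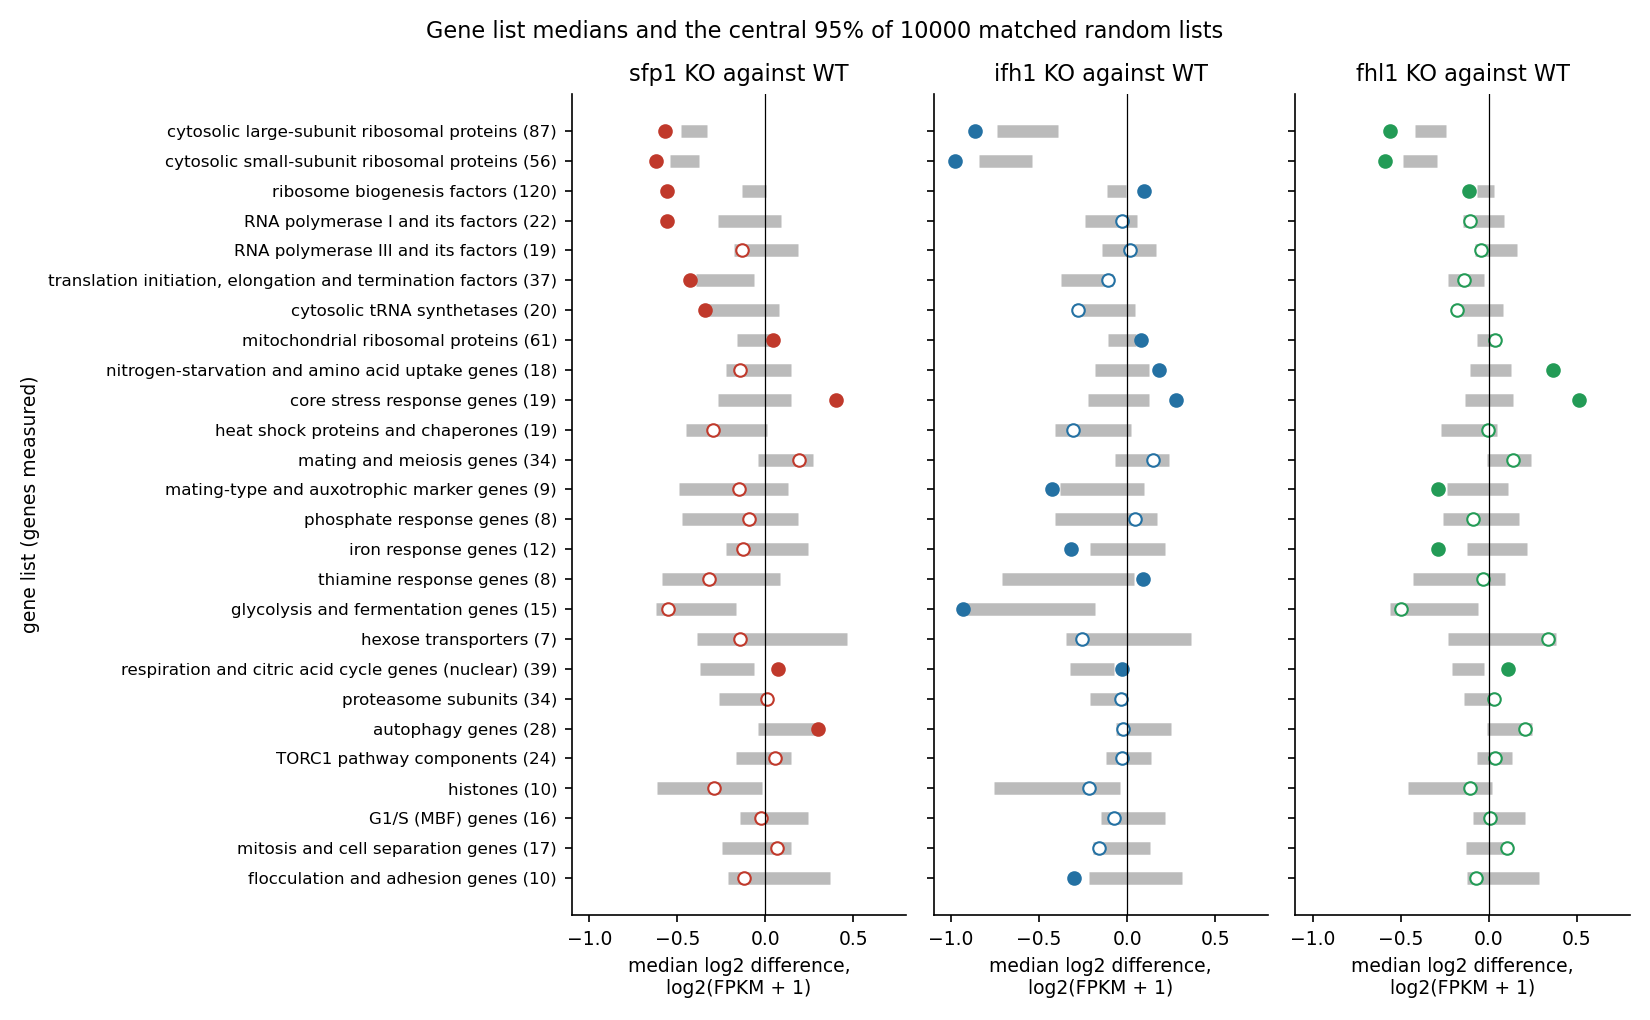
Median log2 ratio of 26 gene lists in each knockout against wild type, over the central 95% of 10000 random lists matched on mean expression (grey bars); filled points lay outside the bar and open points inside. The respiration median of the ifh1 knockout had the opposite sign with quantile normalization. The biogenesis median of the fhl1 knockout was 0.02 with scaling to the sum outside ribosomal protein genes, but −0.13 relative to the median of all genes.

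The 3 comparisons among knockouts asked which differences from wild type were particular to one regulator. Between the sfp1 and ifh1 knockouts, ribosome biogenesis factors and ribosomal protein genes differed in opposite directions. Biogenesis factors were lower in the sfp1 knockout (median −0.66, 119 of 120 below 0, 15 at least 2-fold), as with dbp9 (42.7 against 114.8 FPKM) and nhp2 (321.0 against 840.1 FPKM). Ribosomal protein genes were higher in the sfp1 knockout (median 0.35, random range 0.09 to 0.24, 126 of 142 above 0), as with rps1001 (3356 against 1742 FPKM, 0.95), rps2601 (0.89) and rps1402 (0.88). That median was 0.08 with quantile normalization. The small-subunit list (0.42) was above its random range. The large-subunit list (0.31) was inside its own, at the 93.75th percentile. It was above without the expression minimum, with genes of at least 300 bp and with random lists also matched on length. The RNA polymerase I list (−0.31, and −0.63 without the 6 genes under other names), with nuc1 at −1.17 and rpa43 at −0.97, was lower in the sfp1 knockout, as were RNA polymerase III genes (−0.17), with rpc2 at −0.67, translation factors (−0.32), with tif11 at −0.88, and thiamine genes (−0.20), with thi9 at −1.14. Core stress (0.38), marker (0.46), iron (0.26), autophagy (0.31) and mitosis and separation genes (0.23) were higher, with gst2 at 1.84, lys3 at 1.10, atg12 at 1.23 and adg2 at 0.57. Glycolysis genes (0.34, 14 of 15 above 0) were inside their range, but above when random lists were drawn outside ribosomal protein genes or also matched on length. The calls of the thiamine and RNA polymerase III lists ended with quantile normalization, that of the marker list without the expression minimum and that of the iron list at a mean of at least 10 FPKM.

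The largest single differences between these 2 knockouts, chosen after the values were seen, were gdh2 (524.5 against 48.4 FPKM, 3.41), aes1 (505.4 against 50.3, 3.30), vht1 (1293 against 272.8, 2.24), SPBPB10D8.01 (2.18) and SPAC27D7.09c (1.92). Lower in the sfp1 knockout were the permease genes aat1 (34.6 against 233.2, −2.72), SPAC1039.01 (−2.28) and per1 (43.4 against 200.8, −2.19), with str3 (−2.44) and efm6 (−2.11). At the 2-fold limit, 116 genes were higher and 98 lower in the sfp1 knockout, with bounds apart for 56 and 60. With scaling to the sum outside ribosomal protein genes these were 87 and 134 (39.4% higher, against 54.2%).

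Between the sfp1 and fhl1 knockouts, ribosomal protein genes had a median of −0.02, inside the random range. It was above that range under 6 other settings: quantile normalization (0.05), midpoints of the bounds (0.06), no expression minimum, a mean of at least 10 FPKM, genes of at least 300 bp, and random lists also matched on length. The large-subunit list (0.01), with 44 of 87 genes above 0 and rpl1603 at 197.0 against 72.5 FPKM (1.43), was above its own range, but not with midpoints of the bounds. Biogenesis factors were lower in the sfp1 knockout (−0.45, 117 of 120 below 0), with dbp9 at 42.7 against 95.7 FPKM and nhp2 at −1.02. The RNA polymerase I list (−0.33, and −0.51 without the 6 genes under other names; nuc1 −1.01), translation factors (−0.23, tif213 −0.74) and all 19 heat shock genes (−0.28, mas5 −1.03, hsp16 −0.85) were lower as well. Nitrogen-starvation and uptake genes were lower too (−0.26), 6 of them at least 2-fold, with isp4 at 28.9 against 185.6 FPKM (−2.64) and per1 at −2.51. Marker (0.20), autophagy (0.15) and glycolysis (0.12) lists were above matched lists, autophagy not at a mean of at least 10 FPKM and glycolysis not with midpoints of the bounds. The nitrogen list was inside its range without the expression minimum. The largest other differences, chosen after the values were seen, were gdh2 (2.80), SPBPB2B2.06c (2.51), SPBPB2B2.08 (1.93), aes1 (505.4 against 139.0 FPKM) and SPAC27D7.11c (1.85) on the higher side, and SPAC1039.01 (−2.58), ptr2 (−2.47) and vps32 (−2.46) on the lower side. At the 2-fold limit 56 genes were higher and 90 lower, with bounds apart for 20 and 37. Simulated tables without any difference had means of 74.3 and 74.1, with bounds apart 18.8 and 19.2.

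Between the ifh1 and fhl1 knockouts, ribosomal protein genes were lower in the ifh1 knockout (median −0.35, 134 of 142 below 0), with rpp202 at 4522 against 9679 FPKM, rps1402 at −0.89, rpl3002 at −0.82 and rps902 at −0.73. With quantile normalization the median was −0.02, still below the random range of the combined list. The large-subunit and small-subunit lists, at −0.34 and −0.39 before it, were then at −0.01 and −0.02 and inside their ranges. Midpoints of the bounds ended the large-subunit call too. Biogenesis factors were higher in the ifh1 knockout (0.22, 115 of 120 above 0), with spb4 at 0.46 and nop52 at 0.42. Nitrogen-starvation and uptake genes (−0.33, ptr2 −0.77, isp4 −0.76), core stress genes (−0.26, hsp9 −0.90) and heat shock genes (−0.28, 18 of 19 below 0, hsp104 −1.13, ssa1 −1.02) were lower in the ifh1 knockout. RNA polymerase I (0.05, and 0.15 without the 6 genes under other names; rpa43 0.41), translation factor (0.05) and thiamine (0.11) lists were above matched lists, and mitosis and separation genes (−0.17) were below. The largest other differences, chosen after the values were seen, were str3 (1.72), SPBPB2B2.06c (1.41), vps32 (−2.46), SPBPB10D8.01 (−1.60), the hexose transporter gene ght5 (98.3 against 292.1 FPKM, −1.56), dgc1 (−1.52) and aes1 (−1.45). At the 2-fold limit 19 genes were higher and 65 lower, 31 of the latter shorter than 300 bp, and bounds lay apart for 3 and 13. All 4 counts were below the means of simulated tables without any difference (74.3 and 74.1, with bounds apart 18.8 and 19.2). Those means may be too high for this pair, as the bounds gave more variance than was seen among long genes (0.111 against 0.075). They cannot show that single differences were no more than noise.

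In these 3 comparisons the fixed rule mostly named very short genes listed at 0 in one knockout. Such genes were SPAPB1A11.05, SPAC27E2.14 (5255 FPKM), nce101, min8 (25.1) and SPAC19D5.10c (10.8) between sfp1 and ifh1. Between sfp1 and fhl1 they were SPAC11D3.20, SPCC417.03, mfm3 (523.0), SPBC336.16 (13.9) and SPAP27G11.11c (11.5). Between ifh1 and fhl1 they were SPAC11D3.20, SPAC27E2.14 (3215 FPKM), mfm3, SPAP27G11.11c (22.7), SPBC336.16 (13.5) and SPAC1093.07 (12.2).

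**Figure D3:**
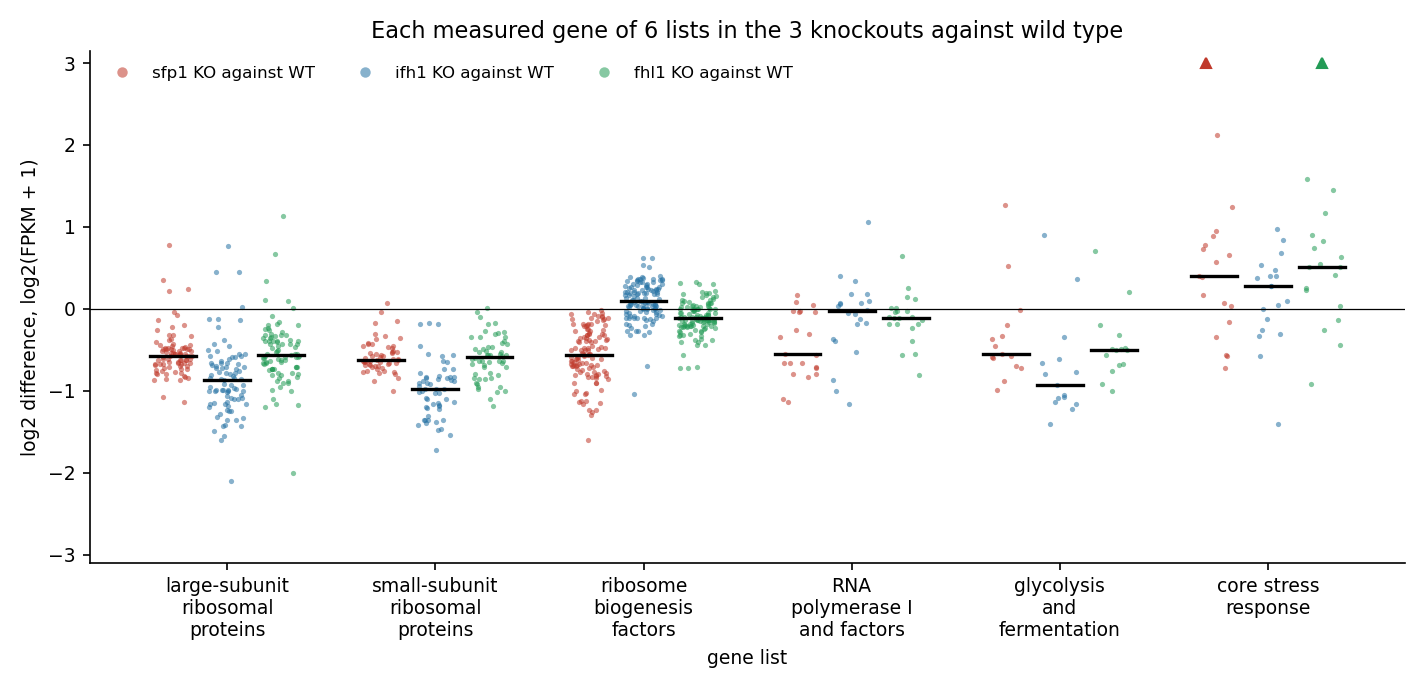
Log2 ratio of each gene of 6 lists in the 3 knockouts against wild type, with black bars for medians. The zym1 values of the sfp1 and fhl1 knockouts, where wild type was listed at 0, lay beyond the axis limit of 3 and are drawn as triangles; with quantile normalization the ribosomal protein medians were closer to 0, at −0.11, −0.17 and −0.12.

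Genes shared between knockouts were counted last, to ask how far the 3 knockouts differed from wild type in the same genes. At the 2-fold limit, 39 genes were higher in all 3 knockouts, among them mei2, ubi4, rtc3, mel1 and nrg1. Others of the 39 were genes shorter than 300 bp listed at 0 in wild type, such as lam4, SPBC21B10.15 and SPBC713.14c. Lower in all 3 were 9 genes, including SPBPB10D8.01, met1, cys2, rpl2701, SPAC8E11.10 and the short gene SPAC922.09, listed at 0 in each knockout. No range was simulated for genes shared by all 3 knockouts. Pairs shared 48 higher and 16 lower genes for sfp1 and ifh1, 69 and 12 for sfp1 and fhl1, and 53 and 27 for ifh1 and fhl1. Opposite directions were met in 3, 5 and 3 genes. All 3 ratios use the same wild-type values, which alone gave shared genes in 100 simulated tables without any difference, built from the bounds. Each pair of knockouts had a mean of 36.0 shared higher genes (lowest to highest 22 to 53) and 8.91 shared lower genes (4 to 15). Above these ranges were the 69 shared higher genes of sfp1 and fhl1 and the 16 and 27 shared lower genes of the pairs with ifh1, the 16 by 1 gene. The counts of 69, 16 and 27 depended on the setting, and ranges were simulated for the main one alone. With genes of at least 300 bp they were 42, 10 and 21, and with scaling to the sum outside ribosomal protein genes 92, 9 and 17. The correlations of the log2 ratios were 0.51, 0.57 and 0.60 (simulated mean 0.498, lowest to highest 0.316 to 0.634). Their covariances were 0.162, 0.1803 and 0.170 (simulated mean 0.116, 0.0874 to 0.195), above the mean in each pair and inside the range. Among genes of at least 1200 bp and more than 20 FPKM, the bounds gave a variance of 0.111 between the ifh1 and fhl1 knockouts. The observed variance was 0.075, so these ranges may be too wide. A value inside them does not show that the wild-type values alone gave the sharing. With 1 wild-type value per gene, the shared part cannot be split into knockouts and wild type.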

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

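Ribosome biogenesis factors and 3 single genes stood out because 2 knockouts lay on opposite sides of wild type, each with 1 value per genotype, so that the difference was not tested; the lower ribosomal protein genes were weighed as well. Of the tests named here, those of abundant transcripts as a partial cause and of an expression trend in the sfp1 knockout library were fixed before the values they measure were seen; the other tests were chosen only after the result was seen.

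Ribosome biogenesis factors differed by −0.66 between the sfp1 knockout (−0.56) and the ifh1 knockout (0.10), and by 0.22 between the ifh1 knockout and the fhl1 knockout (−0.11). With scaling to the sum outside ribosomal protein genes the fhl1 value was 0.02, and −0.13 relative to the median of all genes. Intervals here and below come from 10000 draws that resampled genes, or from the random lists, and not from cultures. They are narrower than the spread over single genes, and resampling takes genes that share their regulation as independent. A wild-type library that stands apart could not give the difference of sfp1 from both other knockouts, as those ratios hold no wild-type value. The value of that difference closer to 0 was −0.45 (interval −0.51 to −0.38). An expression-dependent trend of the sfp1 knockout library could not account for it either, since random lists of matched expression had a median of −0.0621 (−0.135 to 0.0042). The genotype itself may be the cause, a candidate explanation that 1 value per genotype leaves open to differences between cultures.

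Ribosomal protein genes were lower in each knockout. Short-gene scaling of FPKM was excluded as the cause, since from midpoints the value closest to 0 of the 3 knockouts was −0.54 (−0.57 to −0.49). Ribosomal protein genes were lower than random lists of matched expression by a value closest to 0 of −0.28 (−0.38 to −0.23). This cannot exclude a general loss of abundant transcripts as the whole cause, because the matching was incomplete among the most abundant genes. In the highest expression bin, 127 ribosomal protein genes had a median level of 3693.8 FPKM, against 1940.3 for genes outside the lists. Glycolysis genes had similar medians (−0.55, −0.93 and −0.50 in the sfp1, ifh1 and fhl1 knockouts). As a part of the cause this loss cannot be told apart either: abundant genes outside the lists had up to 0.467 (0.198 to 0.720) of the ribosomal protein difference. A wild-type library that stands apart has no part in the difference between knockouts, which reached 0.35 (0.31 to 0.41), as those ratios hold no wild-type value. For the part that the knockouts share such a library cannot be told apart, with abundant genes outside the lists at −0.0671 (−0.196 to 0.0654) in their highest knockout. The genotype may account for the lower level in the ifh1 knockout against the other knockouts. With quantile normalization, though, the sfp1 to ifh1 difference was 0.08 and that of ifh1 to fhl1 was −0.02. The combined list stayed outside its random range in both, while the subunit calls of ifh1 to fhl1 ended. The shared part could come from the genotypes, from the single wild-type column or from a general loss of abundant transcripts, and these values cannot tell them apart.

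SPAC1039.01, an amino acid permease gene, differed by −2.28 between the sfp1 knockout (−1.18) and the ifh1 knockout (1.09) and by −2.58 between the sfp1 and fhl1 knockouts (1.40 in the latter); the difference was not tested. The gene aes1 differed by 3.30 between the sfp1 knockout (1.98) and the ifh1 knockout (−1.32), and the permease gene per1 by −2.51 between the sfp1 knockout (−1.46) and the fhl1 knockout (1.05); these differences were not tested.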

How the results depend on the processing

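No paired analysis was possible because the table held 1 value per genotype. No gene taken by the 2 naming rules as at least 2-fold different reversed its direction; pfl2 in the ifh1 knockout and, outside the rules, met26 in the sfp1 knockout were lower and turned higher with quantile normalization. With size factors or a pseudocount of 5 all 65 list values outside their range stayed there. A pseudocount of 5 gave fewer higher genes in the ifh1 knockout (38), the fhl1 knockout (79), sfp1 against ifh1 (77), sfp1 against fhl1 (36) and ifh1 against fhl1 (12), and shared higher genes of 21 (sfp1 and ifh1), 41 (sfp1 and fhl1) and 29 (ifh1 and fhl1), with 7 shared lower genes for sfp1 and fhl1; it shrinks ratios of low values by construction. With a mean of at least 10 FPKM, which tests fewer genes, 97, 46 and 77 genes were higher in the sfp1, ifh1 and fhl1 knockouts and 10 in ifh1 against fhl1; shared genes were 25 higher and 10 lower (sfp1 and ifh1), 40 and 7 (sfp1 and fhl1) and 32 higher (ifh1 and fhl1). Quantile normalization gave 62 lower genes in the ifh1 knockout, 3 fixed lists below their range in the sfp1 knockout, and a reversed respiration median in the ifh1 knockout (0.1366). Of 65 list values 55 stayed, 9 weakened and 1 reversed. That normalization removes shifts of the most abundant genes by construction. Scaling to the sum outside ribosomal protein genes gave 56 lower genes in the sfp1 knockout, 153 higher and 54 lower in the ifh1 knockout, and reversed the biogenesis median of the fhl1 knockout (0.01834) and the respiration median of the ifh1 knockout (0.2719); shared genes were 89 higher and 9 lower (sfp1 and ifh1), 7 lower (sfp1 and fhl1), and 82 higher and 17 lower (ifh1 and fhl1). Its single factor per genotype raised ratios to wild type and lowered those of sfp1 against ifh1. Relative to the median of all genes, these biogenesis and respiration medians were −0.1308 and −0.006207, so neither sign turned. Midpoints of the bounds, chosen like the next 3 after seeing the data, gave 80 higher genes in the fhl1 knockout, 35 lower in ifh1 against fhl1 and a reversed respiration median in the ifh1 knockout (0.05551); the cause was not tested. Genes of at least 300 bp, fewer genes, gave 80 higher in the fhl1 knockout, 12 higher and 34 lower in ifh1 against fhl1, 10 shared lower genes for sfp1 and ifh1 and 42 shared higher for sfp1 and fhl1. Requiring bounds apart left 49 higher and 64 lower genes in the sfp1 knockout, 15 and 59 in ifh1, 21 and 14 in fhl1, 56 and 60 in sfp1 against ifh1, 20 and 37 in sfp1 against fhl1, and 3 and 13 in ifh1 against fhl1. Random lists also matched on length put 5 lists above their range in the fhl1 knockout instead of 3, adding hexose transporters and mitosis genes, and put glycolysis below in the sfp1 and fhl1 knockouts, as did random lists outside ribosomal protein genes; the cause was not tested. Not run for lack of replicate columns were fits with 2 genotypes alone, variance trends and robust variants, adjusted p thresholds, rotation and estimated-correlation list tests, a replicate block, leaving out replicates and a split of the wild-type columns. A rule asking every knockout column to lie beyond wild type was the same as the main one. Depth limits single genes more than lists: bounds at 5 to 20 fragments reached about 80% of the midpoint.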

Other observations

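Some single genes outside the fixed rules, chosen after their values were seen and giving no result for the pathways they belong to, are listed here in the order wild type, sfp1, ifh1 and fhl1 knockout. The cysteine synthesis gene cys2 stood at 442.8, 177.2, 169.0 and 212.7 FPKM, and sam1, the S-adenosylmethionine synthetase gene, at 3218, 1467, 1289 and 1897. The ATP sulfurylase gene sua1 was at 1748, 1042, 842.3 and 1129 and met10 at 456.7, 256.9, 268.4 and 297.4, while met16 had log2 ratios of 0.05, −0.05 and −0.02. The methionine synthesis gene met26 was at 5294, 4837, 2523 and 3688, and in the sfp1 knockout it was above wild type with quantile normalization. The gene ste11, for a transcription factor that starts sexual development, was at 43.1, 118.2, 78.0 and 79.8 and map1 at 2.98, 9.09, 8.86 and 8.53. The mating and meiosis list that holds both was inside its random range in each knockout, and the M-factor gene mfm3 was listed at 0 in the sfp1 and ifh1 knockouts.

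Among uptake genes, also chosen after their values were seen, put4 was at 161.9, 83.3, 224.2 and 302.5 FPKM in the same order and isp5 at 39.7, 28.5, 73.1 and 104.3. The genes ptr2 (43.9, 25.0, 83.2 and 143.0) and isp4 (39.2, 28.9, 109.0 and 185.6) had the same order of genotypes. Other uptake genes did not: nrg1 was higher in all 3 knockouts (log2 2.13, 1.39 and 1.57) and SPBPB10D8.01 lower in all 3. Of the genes for ammonium use, gdh1 was at 1461, 737.9, 505.2 and 831.2 and gln1 at 1146, 596.1, 712.5 and 809.2.

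Of the tests of hypotheses given here, the local effect at fhl1 and the first HomolD comparison were fixed before their values were seen, and the other 3 tests were chosen only after the result was seen. The gene vps32 lies 427 bp from fhl1 and was at 2.51 in the fhl1 knockout. In the knockout with an intact fhl1 locus that lay farther from 0 it was at 0.0522. Other genes around fhl1 in that knockout were SPAC1142.09 (2.66; 5.33 FPKM, listed at 0 in wild type), ctr5 (1.06), cgs1 (0.92), get3 next to vps32 (0.05) and SPAC8C9.04 (−0.31). A local effect of the deletion and the loss of Fhl1 as a regulator would both give the vps32 values, so that the local effect cannot be told apart. Short-gene scaling was excluded, with 2.47 from midpoints.

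The HomolD box, a promoter element of fission yeast ribosomal protein genes, was looked for within 300 bp upstream of 4611 genes. It was found for 89 of 140 ribosomal protein genes and 34 of 4471 others, among them btf3, tma19 and sam1. These 34 still included ubi2 and ubi5, which encode ubiquitin fused to ribosomal proteins, and cpc2, which encodes the ribosomal protein RACK1. The 34 others had medians of −0.34, −0.50 and −0.36 in the sfp1, ifh1 and fhl1 knockouts, with 29, 30 and 29 below 0. Against random lists that could contain ribosomal protein genes, the percentiles were 27.75, 3.79 and 0.52, the last below the range, and whether the box goes with a lower level cannot be told apart from chance on that test. Against random lists drawn outside ribosomal protein genes the highest percentile was 0.82. Without ubi2, ubi5 and cpc2 the other 31 genes had medians of −0.31, −0.47 and −0.32 and a highest percentile of 1.91, so a lower level of genes with the box is consistent with these 2 comparisons. Ribosomal protein genes without the box had medians of −0.62, −0.97 and −0.57, and those with it −0.58, −0.93 and −0.58.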
